A study of Mus musculus with 2 samples.

How the data were processed

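Messenger RNA sequencing, with an Illumina mRNA preparation kit, was run on mouse embryonic stem (ES) cells that carry the 2C::tomato fluorescent reporter and had been sorted by flow cytometry into reporter-positive and reporter-negative cells. There was 1 library per sorted population, so 2 libraries in all. The cells carry floxed alleles of Kdm1a, the gene of the histone demethylase LSD1, with a CreERT transgene, and were grown on gelatin under hygromycin, per the labels' protocols.

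The authors deposited 1 coverage track per library, in which each value is the number of aligned reads over a base, and the signal is not scaled to depth. Bowtie and the mouse build mm9 are named in the submitters' processing notes. The version, the alignment settings and the filters are not given in the sources used here. Per the file headers each track was made from a sorted BAM file. Bases without reads are listed at 0, strand is not kept, and no replicates were pooled.

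The coverage was decoded into alignments. A track made of alignments of 1 length without gaps can be solved exactly, since each step in coverage is a start or the end of an earlier start. With a length of 72 bases every start count in both tracks came out as a whole number of at least 0, and the shortest isolated covered block was 72 bases. The tracks therefore hold ungapped alignments of 72 bases, and reads that cross a splice junction are not among them. The same start pattern recurred at separate places in the genome, so reads that match several places were listed at each of them. Totals are therefore alignments, not reads.

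Repeated stretches were found by comparing the start counts of both libraries, base by base, over stretches of 64 bases with at least 8 bases holding starts and at least 20 starts, in both orientations. No stretch occurred at more than 20 places. Sequences with more copies than that are either left out of the tracks or listed at part of their places, and transcripts of abundant interspersed repeats were not analysed here. Stretches found at 2 or more places held 25.5% of the alignments of the positive library and 25.7% of those of the negative library. Where coverage is low no distinctive stretch can be defined, so an absence of repeated stretches there says nothing about copy number. Alignments in no distinctive stretch were kept where repeated stretches were left out, so their copy number is open.

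The gene annotation at hand is GENCODE release M21, made for the build mm10 (GRCm38). Its coordinates cannot be used on mm9 chromosomes, so reads were not assigned to nuclear genes. The comparisons by gene, by the 21 gene lists fixed before the data were examined and by reads outside genes were not made, and neither were their scalings by TMM or by size factors. The Kdm1a level was not analysed here for the same reason. The comparison by genomic window, fixed for this case, became the main one. The exception is the mitochondrial chromosome, which is 16299 bases long in the files and is the same sequence record in both builds. As a check, alignments crossing the starts of 13 mitochondrial genes by at least 10 bases on each side were counted. There were 5235 at the annotated starts, against at least 7450 and a median of 19837 when the annotation was shifted by 50 to 300 bases either way. The fewest of all, 4852, were at a shift of 15 bases upstream, so the check does not resolve shifts of that size. It replaced a first measure, the share of alignments wholly inside genes, which was highest at a shift of 10 bases (97.5%, against 97.4% without a shift) and did not separate small shifts.

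Alignments were counted by start in 10 kb windows. The positive to negative ratio was taken of the shares of all alignments in each library, with an exact conditional binomial (Clopper-Pearson) 95% interval. Windows with at least 20 alignments in both libraries together were compared, and a window passed the size rule if its ratio was at least 2-fold and its interval excluded 1. A 4-fold rule was applied in the same way. With 1 library per group there is no replicate check, no p-value is given, and every statement describes these libraries. Intervals cover counting error only, and reads without molecular identifiers are not independent molecules, so they are too narrow. Reads listed several times within a region narrow its interval further. Against a count of 0 a ratio is given with 3 counts in place of 0 over the region, beside the lower bound of its interval.

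The windows named are the 5 highest and the 5 lowest by the bound of the interval nearest to 1, among windows with at least 50 alignments, a rule fixed before the data were examined. Windows at least 4-fold higher were then joined into regions where they lay within 100 kb of each other, and the 15 regions with most alignments are listed. This joining, the search for repeated stretches and any other region named were chosen after the data were seen. Mitochondrial alignments were given to a gene if they lay wholly inside 1 annotated gene. Overlapping genes on the same strand, such as mt-Atp8 and mt-Atp6, cannot be separated over their overlap. Strand is unknown, so alignments given to mt-Nd6, on the minus strand, may come from either strand.

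The decoding, the search for repeated stretches and the size rule were tested on simulated data. Independent Poisson counts were drawn for the real windows with no change. The 2-fold rule then passed 191 windows as higher and 206 as lower of 48349, and the 4-fold rule passed 12 and 7. For the same comparison, of 100 windows raised 3-fold 97% passed the 2-fold rule and of 100 windows lowered 3-fold 79% did. At 6-fold the shares were 100% and 87%. Alternatives were windows of 50 kb, each position counted 1 time, scaling by the median ratio, and, chosen after the data were seen, other minimum counts, thinning of the deeper library and down-weighting or leaving out repeated stretches. Counting positions cannot follow differences where start positions are nearly used up, as on the mitochondrial chromosome and in short dense blocks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.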

Results

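The transcriptomes of reporter-positive and reporter-negative mouse ES cells were compared, with 1 RNA-seq library for each population. The 2C::tomato reporter is driven by regulatory sequence of the endogenous retrovirus MuERV-L, which is transcribed in the embryo at the 2-cell stage. The question was how the transcripts of cells with an active reporter differ from those of cells of the same background without it. The positive library held 37059813 alignments of 72 bases, at 8326713 distinct start positions. The negative library held 33833215 alignments at 7193195 positions. Each population has 1 library, so no difference given here has a replicate check, and intervals are 95% counting intervals. Alignments covered 87.7 Mb of mm9 in the positive library and 72.6 Mb in the negative library.

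Most of the windows compared were covered alike in both populations, and the windows past the size rule were mainly higher in the positive library. Of 48349 windows of 10 kb with at least 20 alignments, 45000 (93.1%) had a ratio within 2-fold. By the size rule 2232 windows were at least 2-fold higher in the positive library and 400 were at least 2-fold lower. At 4-fold, 817 windows were higher and 30 were lower. Counted by position, 1774 and 697 windows were higher and 139 and 8 were lower, so most of the lower calls went under that setting. In simulated libraries of these depths, independent counting error alone gave 191 higher and 206 lower windows at 2-fold and 12 and 7 at 4-fold. The lower windows exceeded that level far less than the higher ones did. The simulated counts were independent, while real reads share start positions and are listed at several places. Real counting error is therefore wider, and whether the lower windows exceed it is not shown. The simulation also assumed no general shift, while all windows with 20 to 49 alignments had a ratio of 1.21 as a group. Such a shift moves thinly covered windows toward higher calls and away from lower ones. How many calls it accounts for was not tested. With at least 50 alignments, 934 windows were at least 2-fold higher and 147 lower, and at 4-fold 374 and 0. Among 9492 windows with at least 1000 alignments, 99.4% were within 2-fold, 51 were at least 2-fold higher and 2 were at least 2-fold lower. Across the 22959 windows with at least 200 alignments, log2 counts (pseudocount 0.5) correlated with Pearson's r of 0.963 and Spearman's rho of 0.973. These are correlations across windows, which are not independent replicates.

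**Figure D1:**
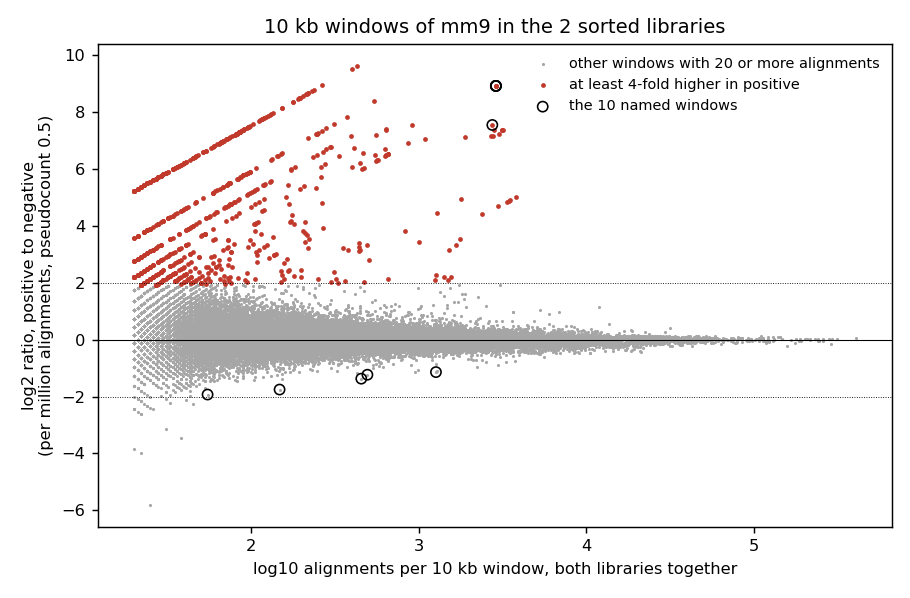
Each point is a 10 kb window of mm9 with at least 20 alignments. The horizontal axis is the log10 number of alignments in both libraries together, and the vertical axis is the log2 positive to negative ratio of library shares with a pseudocount of 0.5. Dotted lines mark 4-fold, red points are the 817 windows at least 4-fold higher in the positive library, and open circles mark the 5 highest and 5 lowest windows by the bound of their interval. The red points reach far above the cloud while few windows fall below the lower line.

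The 817 windows at least 4-fold higher in the positive library fell into 470 regions, of which 373 were single windows and 37 held 4 or more windows. They took up 0.370% of the alignments of the positive library (136963) and 0.0177% of those of the negative library (5993). The negative library had no alignment in 201 of these windows. The 15 regions with most alignments held 68.1% of the positive alignments in all 470. Values of a region sum its windows that were at least 4-fold higher and leave out the windows between them. Windows were picked for their high ratio, so the ratios of thinly covered regions are biased upward. Unplaced and unlocalised sequence held 10.5% of the 817 windows (86) but 0.583% of the windows compared (282). Some of these windows share repeated stretches with windows of chromosomes 1 and 5, so they are not independent of them.

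A 40 kb region of chromosome 10 stood furthest apart between the populations. It spans 103600001 to 103640000 and holds the 4 windows with the highest interval bounds. Each of them had between 2888 and 2893 alignments in the positive library and 5 in the negative library. The region as a whole had 11561 alignments in the positive library and 20 in the negative library, a ratio of 528. Since the same reads are listed several times there, its interval is better taken with each alignment weighted by its number of places, which gave 623 (243 to 2290). Weighted counts were rounded to whole numbers in each window, so with so few negative alignments the ratio of 623 is coarse. In each window over 99% of the alignments lay in 1 covered block, at 103606792 to 103607996, 103615301 to 103616505, 103623809 to 103625013 and 103632318 to 103633534. Identical stretches in the region were most often 8509 bases apart, and repeated stretches held 98.8% of its alignments. The 4 windows thus carry copies of much the same signal and are not independent of each other. When each start position was counted 1 time, which limits how high short dense blocks can count, the region's ratio was 155 (95.2 to 271). With repeated stretches left out, 135 alignments, only 18 of them in stretches found at 1 place, stood against 0. The ratio was 40.96 with 3 counts in place of 0, and the lower bound of the interval was 32.9.

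Another region of chromosome 10, at 99760001 to 99860000, had the most alignments of any region higher in the positive library. It had 22507 in the positive library and 723 in the negative library, a ratio of 28.4 (26.4 to 30.6). Repeated stretches held 90.7% of its alignments and were found at up to 15 places. The 13 windows of these chromosome 10 regions were joined by shared stretches into 1 family with a ratio of 41.9 (38.9 to 45.1). That interval counts the same reads several times and is too narrow.

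On chromosome 7, a pair of neighbouring regions was higher in the positive library, at 11370001 to 11760000 and at 11890001 to 12200000. The first had 14318 alignments in the positive library and 79 in the negative library, a ratio of 165 (133 to 209). The other had 12644 and 79, a ratio of 146 (117 to 185). Counted by position the ratios were 77.9 and 64.5, and with repeated stretches left out that of the later region was 58.7. Weighted by places the regions had ratios of 173 (117 to 268) and 104 (73.5 to 154). The fifth named window, 11650001 to 11660000, lies in the first of them and had 2743 and 13 alignments, a ratio of 193 (112 to 362). Its ratio was 93.3 counted by position, 474 (84.7 to 18764, from 1 alignment in the negative library) with repeated stretches left out, and 2.70 in 50 kb windows, which take in its neighbours. Shared stretches joined 14 windows of chromosome 7, the first at 11370001, into 1 family with 26933 and 158 alignments. These are nearly all alignments of the pair, so its regions are not independent of each other. The signal did not extend over the whole span of the pair. Of its 83 windows, 15 were at least 4-fold higher, while 6 other windows with at least 200 alignments had 5929 and 5860 alignments, a ratio of 0.924 (0.891 to 0.958).

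**Figure D2:**
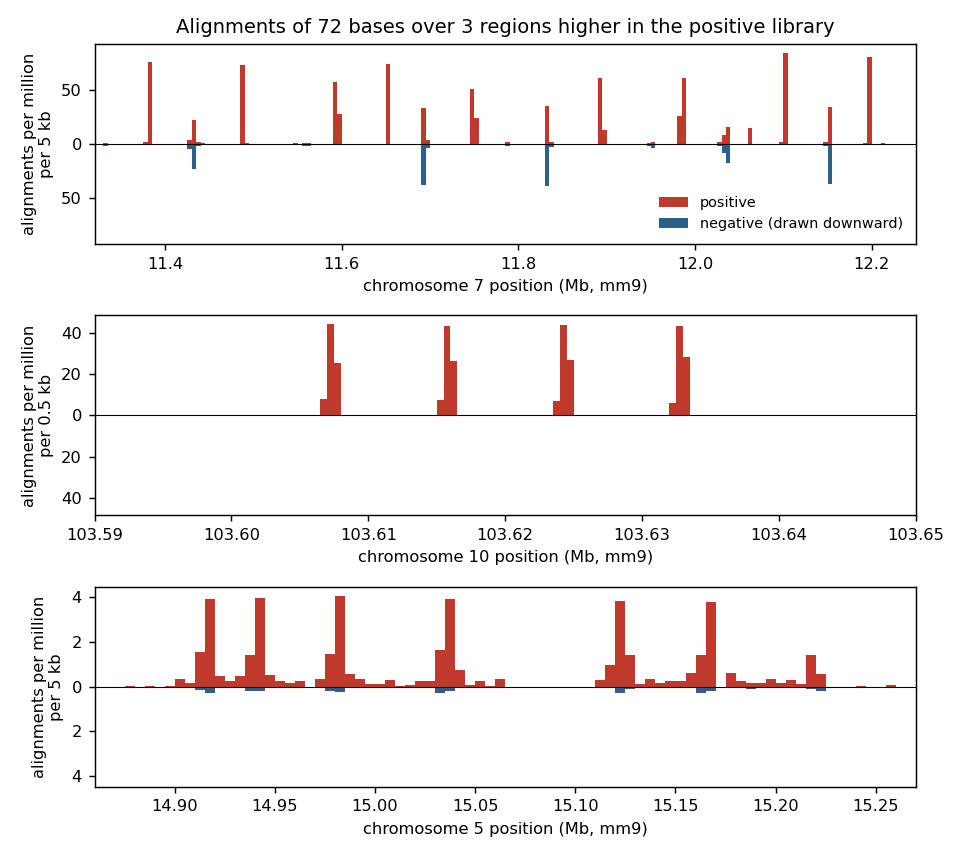
Alignments scaled to library size over 3 regions, with the positive library drawn upward in red and the negative library downward in blue. The horizontal axes are mm9 positions in Mb, and bars sum 5 kb on chromosomes 7 and 5 and 0.5 kb on chromosome 10. On chromosome 7, windows seen almost wholly in the positive library alternate with windows of like height in both, and on chromosome 10 the 4 blocks of the positive library are evenly spaced.

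Further regions were higher in the positive library. On chromosome 5, 40 windows between 94620001 and 96240000 had 6358 alignments in the positive library and 75 in the negative library, a ratio of 77.4 (61.6 to 98.5). A region just before it, at 94060001 to 94510000, had a ratio of 122 (72.7 to 224). With repeated stretches left out its ratio was 232 (79.0 to 1126), from 764 and 3 alignments. Of these only 12 and 1 lay in stretches found at 1 place. Repeated stretches joined windows of chromosome 5 with windows of unplaced sequence. On chromosome 3, 28 windows between 93430001 and 94080000 had 3907 and 41 alignments, a ratio of 87.0 (64.01 to 121). On chromosome 18 the region 80200001 to 80230000 had 2193 and 14 alignments, a ratio of 143 (85.0 to 262). The unplaced region from 1580001 to 2000000 of Un_random had 2185 and 22, a ratio of 90.7 (59.7 to 145).

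The other listed regions had smaller ratios. The ratio was 11.8 (10.4 to 13.4) at chromosome 6, 50540001 to 50580000, and 9.44 (8.35 to 10.7) at chromosome 6, 23100001 to 23120000. Shared stretches joined 5 windows of both regions into 1 family with 6266 and 540 alignments. The chromosome 6 regions are therefore not independent of each other. Repeated stretches held 94.1% of the alignments of both. With these left out, the former had 201 and 15 alignments, a ratio of 12.2 (7.22 to 22.2). The latter had 190 and 0, a ratio of 57.6 with 3 counts in place of 0 and a lower interval bound of 46.4. The ratio was 9.45 (8.25 to 10.9) at chromosome 7, 58190001 to 58250000. It was 21.7 there with repeated stretches left out, from 1333 and 56 alignments. Of these only 3 and 0 lay in stretches found at 1 place, so the copy number of the rest is open. On chromosome 12 the ratios were 4.77 (4.26 to 5.37) at 88810001 to 88840000, 4.61 (4.19 to 5.07) at 88950001 to 89060000 and 5.27 (4.76 to 5.85) at 89160001 to 89390000. With repeated stretches left out, the region from 88950001 was at 30.8. Shared stretches joined 8 windows of chromosome 12, the first at 88830001, into 1 family with 6088 and 1184 alignments. These are most of the alignments of the chromosome 12 regions, which are therefore not independent of each other. The chromosome 12 spans also held densely covered windows that were not 4-fold higher. In the span from 88950001 there was 1, with 557 and 613 alignments and a ratio of 0.830 (0.738 to 0.932). In the span from 89160001 there were 6, with 14430 and 12116 alignments and a pooled ratio of 1.09 (1.06 to 1.11), with single windows from 0.783 to 3.76. These hold more alignments than the 2494 and 432 of the higher windows there.

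Outside the listed regions, 18 regions with at least 200 alignments in the positive library held no repeated stretch. Most of them were covered too thinly to define a distinctive stretch, so their copy number is open. They were looked at after their values were seen. The most covered was chromosome 5, 14910001 to 15220000, with 1488 alignments in the positive library and 95 in the negative library, a ratio of 14.3 (11.6 to 17.8). The region at chromosome 1, 34140001 to 34250000 had a ratio of 5.30 (4.55 to 6.20), and that at chromosome 13, 68260001 to 68500000 had 5.15 (4.28 to 6.24). On chromosome 14, 106840001 to 106890000, 656 alignments stood against 2, a ratio of 299 (82.6 to 2478). On chromosome 4, 73270001 to 73340000, 421 alignments stood against 0. The ratio was 128 with 3 counts in place of 0, and the lower bound of the interval was 104.

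Windows lower in the positive library were fewer, scattered and smaller in effect. The 400 windows at least 2-fold lower fell into 378 places when joined over 100 kb, 357 of them single windows. None of the 37379 windows with at least 50 alignments was at least 4-fold lower, against 374 that were at least 4-fold higher. Among the 5 lowest by interval bound, the window at chromosome 12, 8970001 to 8980000 had 36 alignments in the positive library and 112 in the negative library, a ratio of 0.293 (0.196 to 0.431). The window at chromosome 3, 107540001 to 107550000 had 12 and 43, a ratio of 0.255 (0.122 to 0.492). The window at chromosome 11, 109030001 to 109040000 had 135 and 320, a ratio of 0.385 (0.313 to 0.472), and 87.3% of its alignments lay in 1 block of 104 bases. Counted by position its ratio was 0.726, but so short a block has few start positions to fill, so this value does not measure the difference. The chromosome 12 window was at 0.488 counted by position. The chromosome 12 window was at 0.916 (0.783 to 1.07) when measured over 50 kb. The windows at chromosome 14, 44840001 to 44850000 and chromosome 16, 91220001 to 91230000 had ratios of 0.453 (0.402 to 0.509) and 0.424 (0.349 to 0.514). Counted by position they were at 0.566 (0.485 to 0.661) and 0.474 (0.381 to 0.586), so the former was no longer 2-fold lower. With repeated stretches left out the chromosome 14 window was at 0.374 (0.251 to 0.548). The chromosome 14 window was largely repeated sequence, with 89.4% of its alignments in repeated stretches.

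The mitochondrial chromosome took up a slightly smaller share of the positive library. It held 0.491% of the alignments (0.489 to 0.493) against 0.542% (0.540 to 0.544) in the negative library, a ratio of 0.906 (0.8998 to 0.912). Of its 13 protein-coding and 2 ribosomal RNA genes, 11 had a ratio whose interval lay below 1, 1 above and 3 included 1, and none reached 2-fold. The lowest was mt-Atp8 with 0.670 (0.643 to 0.698), followed by mt-Nd3 with 0.753 (0.712 to 0.797), mt-Rnr1 with 0.762 (0.702 to 0.828) and mt-Atp6 with 0.775 (0.760 to 0.791). mt-Atp8 and mt-Atp6 encode subunits of the mitochondrial ATP synthase, mt-Nd3 a subunit of complex I, and mt-Rnr1 the small ribosomal RNA. mt-Co1, a subunit of cytochrome c oxidase and the most abundant of them, had 51791 and 47446 alignments, a ratio of 0.997 (0.984 to 1.01). mt-Nd5, another complex I subunit, had the highest ratio, 1.08 (1.04 to 1.11). With 1 library per population, differences of this size cannot be set against variation between libraries.

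**Figure D3:**
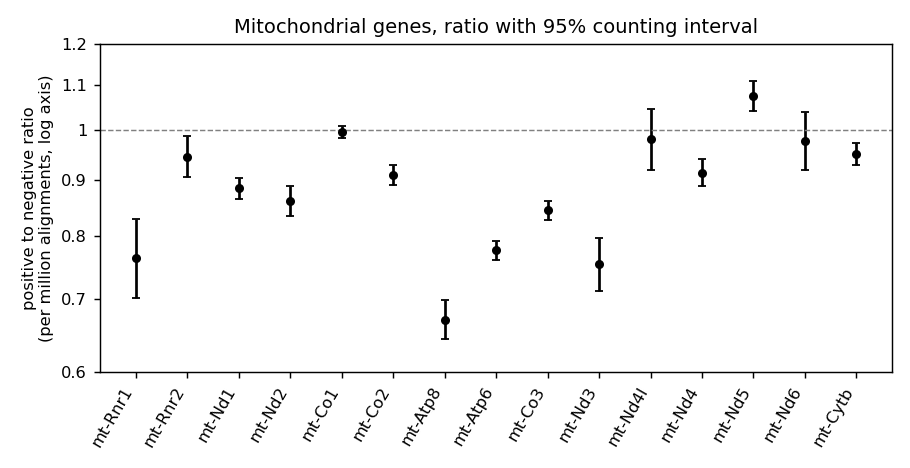
Positive to negative ratio of library shares, on a log axis, for the 15 mitochondrial protein-coding and ribosomal RNA genes. Bars are 95% counting intervals, and the dashed line marks equal levels. mt-Atp8 lies lowest at 0.670 and mt-Nd5 highest at 1.08.

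Whole chromosomes differed little. Over the autosomes and the X chromosome the ratio ran from 0.984 on chromosome 3 to 1.02 on chromosome 10. The X chromosome held 4.98% of the alignments of the positive library and 4.99% of those of the negative library. Sequence of the Y chromosome, placed or not, held 8328 and 8212 alignments, or 0.0225% (0.0220 to 0.0230) and 0.0243% (0.0237 to 0.0248).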

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

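The counts of windows rest on their minimum count and size far more than on scaling or repeats. The windows at least 2-fold higher (2232), 4-fold higher (817), 2-fold lower (400) and 4-fold lower (30) became 1072, 447, 112 and 7 with windows of 50 kb, which are fewer in number. With each position counted 1 time the lower windows became 139 and 8, while the higher ones became 1774 and 697. Of the remaining alternatives, all but median-ratio scaling were chosen after the data were seen. With at least 50 alignments the 4 counts were 934, 374, 147 and 0, with at least 200 they were 183, 113, 12 and 0, and with no minimum they were 4211, 2686, 904 and 499. Higher windows outnumbered lower ones under each of these settings. Median-ratio scaling (a factor of 1.01), thinning, down-weighting by places and leaving out repeated stretches kept all 4 counts within 1.5 times. Of 161 recomputed ratios and shares of named windows, regions and mitochondrial genes, 114 stayed within their counting interval and 46 moved outside it, mostly when positions were counted. 1 reversed, mt-Nd5, at 0.906 with positions counted, a measure that is saturated there: 181900 and 183367 mitochondrial alignments shared 11914 and 11642 positions of 16299 bases, so all 15 genes fell between 0.856 and 0.906. With repeated stretches left out, no finite ratio was had for the chromosome 10 windows from 103600001 or for the chromosome 6 region from 23100001. Depth limits what can be said of windows under 20 alignments, and with 1 library per population none of these settings measures biological variation. No paired analysis was possible because each population has 1 library. No replicate could be left out. Counts by gene, by gene list and of reads outside genes, with their TMM, size-factor, minimum, pseudocount, gene-body and mitochondrial settings, were not run, since no annotation of mm9 was used.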

Other observations

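The test of matched sets was set down before its result was seen, while the families, the bins of coverage and the tests of depth, by distance, of stretches found at 1 place and of the scaling were chosen after. Some of the windows higher in the positive library shared repeated stretches with each other. Among the 817 windows at least 4-fold higher, 161 were joined by shared stretches into 23 families, 19 of which lay on 1 chromosome or scaffold. One family of 11 windows on chromosome 4, first seen at 143100001, had 2313 alignments in the positive library and 16 in the negative library, a ratio of 132 (81.1 to 231). A family of 10 windows on chromosome 7, first seen at 110390001, had 3013 and 18, a ratio of 153 (96.5 to 258). A family of 17 windows joined chromosomes 1 and 5 with unplaced sequence and had 2730 and 32, a ratio of 77.9 (55.0 to 114). The most scattered family had 10 windows on 7 chromosomes and fewer alignments, 373 and 68, a ratio of 5.01 (3.86 to 6.58). Windows of a family list the same reads several times. The family intervals are not weighted by places, so they are too narrow.

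A candidate explanation is that reads listed at several places create these differences. Windows were picked that were at least 4-fold higher by their repeated stretches alone. Of these, 65 had at least 20 alignments in stretches found at 1 place. Their median ratio there was 46.6, and 50 of them were at least 4-fold higher there. Yet 11 were below 2-fold, and summed over all 184 such windows the ratio was 1.63 (1.59 to 1.66), so this explanation stays open for part of the windows. The windows may also lie in repeated sequence more often than others of like depth. Of the 470 regions, 94 had a distinctive stretch in their richest window and could be tested. A repeated stretch was found in 59.6% of the 94. The median of 10000 random sets matched on alignments was 18.1%, and 95% of them were at or below 25.5%. Regions that hold copies of 1 family were counted separately though they list the same reads. They are not independent of each other, which may widen the gap to the random sets. Position in duplicated sequence stays a hypothesis, and the type of sequence is open without an annotation of mm9.

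Sparsely covered windows held relatively more alignments in the positive library. The ratio was 1.49 (1.47 to 1.51) over 65170 windows with 1 to 4 alignments, 1.32 with 5 to 19, 1.21 with 20 to 49 and 0.993 with 1000 or more. A difference in depth acts on all windows by 1 factor, which cancels in these ratios, so it is an unlikely source of 1.49 in sparse beside 0.993 in dense windows. Genomic DNA spread evenly could be a source. In windows under 20 alignments, the excess next to a window of at least 200 alignments was 6.96 times that over 1 Mb away (11.7 before the test was limited to these windows) and 3.85 times with the empty starts of chromosomes left out, against an even spread, but the ratio rose with distance from 1.35 to 1.61, as an even spread would give. Genomic DNA, variation between single libraries and a difference tied to the reporter cannot be told apart with 1 library per population and no map of unsequenced or unmappable windows.

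The scaling to total alignments could favour higher over lower windows. All ratios would have to be divided by 1.98 for the windows at least 4-fold higher and lower to be about equal in number (540 and 552). Of 37290 windows with at least 50 alignments and at least 1 in each library, 97.6% had a ratio below that factor and the median was 1.01, which argues against scaling as the cause, provided that the typical window did not change.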
